A study of Oryza sativa with 30 samples.

How the data were processed

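Rice leaf RNA was measured by strand-specific RNA sequencing in 30 libraries from seedlings grown for 14 days at 26 °C in 13 h light and 11 h dark on 0.5-strength MS medium; 60Co gamma rays were given at 1 Gy per minute. The authors deposited gene values in FPKM, fragments or reads per kilobase of gene, scaled to library size, and per the file headers each table also held the gene length in bases. The aligner, genome build and counting tool are not given in the sources used here. The deposited FPKM values, times gene length, were whole multiples of a constant step in every column (100% of values within 0.01), so the reads per gene could be recovered, and these steps showed that the authors had scaled library sizes separately for 20 libraries (38978 genes listed) and for 10 libraries (40718 genes listed, 36677 in both). A deposited workbook by the authors gave log2 fold changes, p-values with adjusted p-values, and group mean signals as normalised read counts for a selection of 106 genes, and 770 genes for DJ at 40 Gy. These were used for comparison only. All library columns were matched to a sample (0 left), and 1 column of the authors' group means, named K3, was matched to no group and was not used. Replicates are not stated to come from separate plants, so p-values measure the spread between libraries.

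Because the deposited values were FPKM, each set of libraries was fitted with limma 3.58.1 in R 4.3.3 (limma-trend) on log2(FPKM + 1), with a mean for each group and a shared spread, after keeping genes at 1 FPKM or more in at least 2 libraries of the fit (24582 genes with 10 residual degrees of freedom, and 23063 genes with 4). Two-sided p-values were adjusted by Benjamini and Hochberg over all genes of a comparison and called under 0.05. Differences between responses were tested as interactions. Comparisons with 1 library in an arm assume that the lone library varies like the other groups. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of each comparison; of 224 list tests 98 passed with the preset and 9 with the estimated correlation. Members were also counted when adjusted over the list alone. Pairs of single libraries were given no test: each list's median log2 difference was ranked among 10000 random lists matched on mean expression in 20 bins. Genes of a list can vary together, which random lists do not copy, so these ranks are not p-values. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9 and data.table (version 1.17.8) were also used.

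The groups, comparisons, tests, a set of other settings and 15 gene lists were fixed before the data were examined. The lists were DNA damage response and repair, light harvesting, photosystems and electron transport (nuclear), Calvin cycle, chlorophyll synthesis, chloroplast-encoded genes, cold response, proliferating cells, secondary wall and vascular cells, epidermis and cuticle, defence, heat shock proteins, cytosolic ribosome, antioxidant enzymes, and ABA and drought signalling. Members came from 90 identifiers, all 90 found, and from matches of gene descriptions, and 84 members were dropped where the description contradicted the list. The authors' 106 genes formed a further list, which shared 15 of 24 members with light harvesting, 30 of 48 with photosystems, 15 of 38 with Calvin cycle and 10 of 19 with chlorophyll synthesis. Named genes were the genes of the line labels, up to 3 called members of each list with the largest change, and the 5 largest rises and 5 largest falls among called, described genes with a group mean of 5 FPKM or more and no overlap between groups (20 FPKM or more in the higher library for single libraries). Genes from the label list and the 4 DNA damage genes are given in other groups for comparison, chosen after their values were seen, as were the genes that rose in ATM at 70 Gy, CP29 and PSBO in atr.

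The recovered reads, about 10364400 to 16477100 per library, limit the precision but do not alone set it. With about 16413200 reads, atm-1 control replicate 1 had 20514 genes listed at 0. Its Pearson's r across genes was 0.8302 and 0.786 with replicates 2 and 3, which correlated at 0.9397 with each other. Library differences by low read numbers were described as the percent of detected genes with 1 to 10 reads. The fit was tested on simulated data with known changes: at a log2 change of 2, 67.2% of changed genes were recovered for ATM at 70 Gy, 49.3% for the 70 Gy interaction, 38.8% for top6a3, 4.48% for ku70 at 40 Gy and 0 for the 40 Gy interaction. Changes were given only to genes with a mean level of 5 FPKM or more, with independent normal noise. Only 66 or 67 genes were changed at each log2 size of 1, 2 and 4. The top6a3 simulation called 82 genes in all, against 3166 in the real comparison. Adjusted p-values depend on how many genes change, so the rates need not hold where many more do. Transcripts missed in single libraries were not simulated, so the rates do not cover them or genes at lower levels. The other settings fixed at that stage were a filter of 5 FPKM, no filter, a pseudocount of 0.1, median-ratio scaling and robust moderation. Further ones fixed then were only the groups compared, a log2 size of 1, other wild types for top6a3 and an estimated correlation. Also fixed were a replicate block, always fitted with only the groups compared, and leaving out each library whose group held another. Chosen after seeing the data were limma-voom on the recovered reads, library weights, leaving out both libraries with few low-read genes (ATM 70 Gy replicate 3 and atm-1 control replicate 1) and a mean of 20 FPKM or more. No test or fold change used values of both separately normalised sets. Across the sets, levels of the genes of the line labels and genes under 1 FPKM in every library of a line were described, and whole-group profiles of the authors' 106 genes were correlated, gene by gene and in rising order, also with subsets of a group's libraries, as chosen after seeing the data.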

Results

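Leaf RNA of 14-day-old rice (Oryza sativa) seedlings was sequenced in 30 libraries that fell into 16 groups. The lines were the wild type DJ, lines labelled by the DNA damage genes ATM, ATR and KU70, lines labelled by TOP6A3, a subunit of the DNA topoisomerase VI complex, a line labelled as overexpressing TOP6A3 (TOP6A3-OE1), and that line combined with a mutation of ATM (TOP6A3-OE1_atm-2). Seedlings were left untreated, were irradiated with 40 or 70 Gy of 60Co gamma rays and sampled 6 h later, or were kept at 4 °C for 24 h. The untreated groups held 2 libraries of DJ, 2 of ku70, 3 of ATM, 3 of atm-1, 3 of top6a3, 1 of TOP6A3 and 1 of atr. The 40 Gy groups held 2 libraries of DJ, 2 of ku70, 1 of TOP6A3-OE1 and 1 of TOP6A3-OE1_atm-2, the 70 Gy groups 3 of ATM, 3 of atm-1 and 1 of atr, and the cold groups 1 of ATM and 1 of atm-1. The values allowed between about 10364400 reads (the cold ATM library) and 16477100 reads (TOP6A3-OE1_atm-2) to be recovered per library. The values were deposited apart for untreated, 40 Gy, 70 Gy and cold libraries, so every comparison of treated with untreated leaves crosses deposited tables. Those that listed the same genes were joined, and each joined set is called a table below. The ATM, atm-1, TOP6A3, top6a3 and atr lines made up 20 libraries, and the DJ, ku70 and TOP6A3-OE1 lines 10. The joined sets were treated as separately normalised, and tests were made only within each. The ATM, atm-1, TOP6A3, top6a3 and atr libraries differed in how many genes were seen with few reads: genes with 1 to 10 reads made up 1.53% of the detected genes in atm-1 control replicate 1 and 1.70% in ATM 70 Gy replicate 3, against 10.8% to 21.8% in the other libraries of that table. In the DJ and ku70 libraries this share was 1.22% to 8.30%.

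The genes named in the line labels were examined in every library. TOP6A3 (Os03g0284800, chromosome 3, 9797238 to 9799120, genome build not given in the sources used here) stood at 1899 FPKM, from 54910 reads, in the single library labelled TOP6A3, and at 10.3 FPKM or less in the other 19 libraries of its table, including 4.03, 3.57 and 3.84 FPKM in those labelled top6a3. In the other table it was at 5.11 FPKM or less, with 4.49 FPKM in the library labelled TOP6A3-OE1. The transcript of TOP6B (Os09g0279600), the other subunit of the complex, was at 180 FPKM in the library labelled TOP6A3 and between 2.70 and 20.3 FPKM in the other libraries with a read of it. Neither library labelled ku70 at 40 Gy had a read of TOP6B or TOP6A3. KU70 (Os07g0184900), whose product binds DNA ends, was at 24.7 and 37.8 FPKM in the libraries labelled ku70 control and at 7.85 and 15.8 FPKM in those labelled ku70 40 Gy, against 5.31 and 0.319 FPKM in the DJ controls (log2 difference of the controls 3.45, adjusted p = 0.304). ATM (Os01g0106700, chromosome 1, 335809 to 370652), a kinase activated by DNA breaks, was at 6.19, 4.27 and 4.12 FPKM in the ATM controls and at 0.850, 4.54 and 5.23 FPKM in the libraries labelled atm-1 control (log2 difference -0.53, adjusted p = 0.720). ATR (Os06g0724700), a related kinase, was at 0.206 FPKM (7 reads) in atr control and 1.12 FPKM in atr 70 Gy. In the other libraries of that table it was between 1.11 and 5.23 FPKM, except in atm-1 control replicate 1, a library with few low-read genes, where it was listed at 0.

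**Figure D1:**
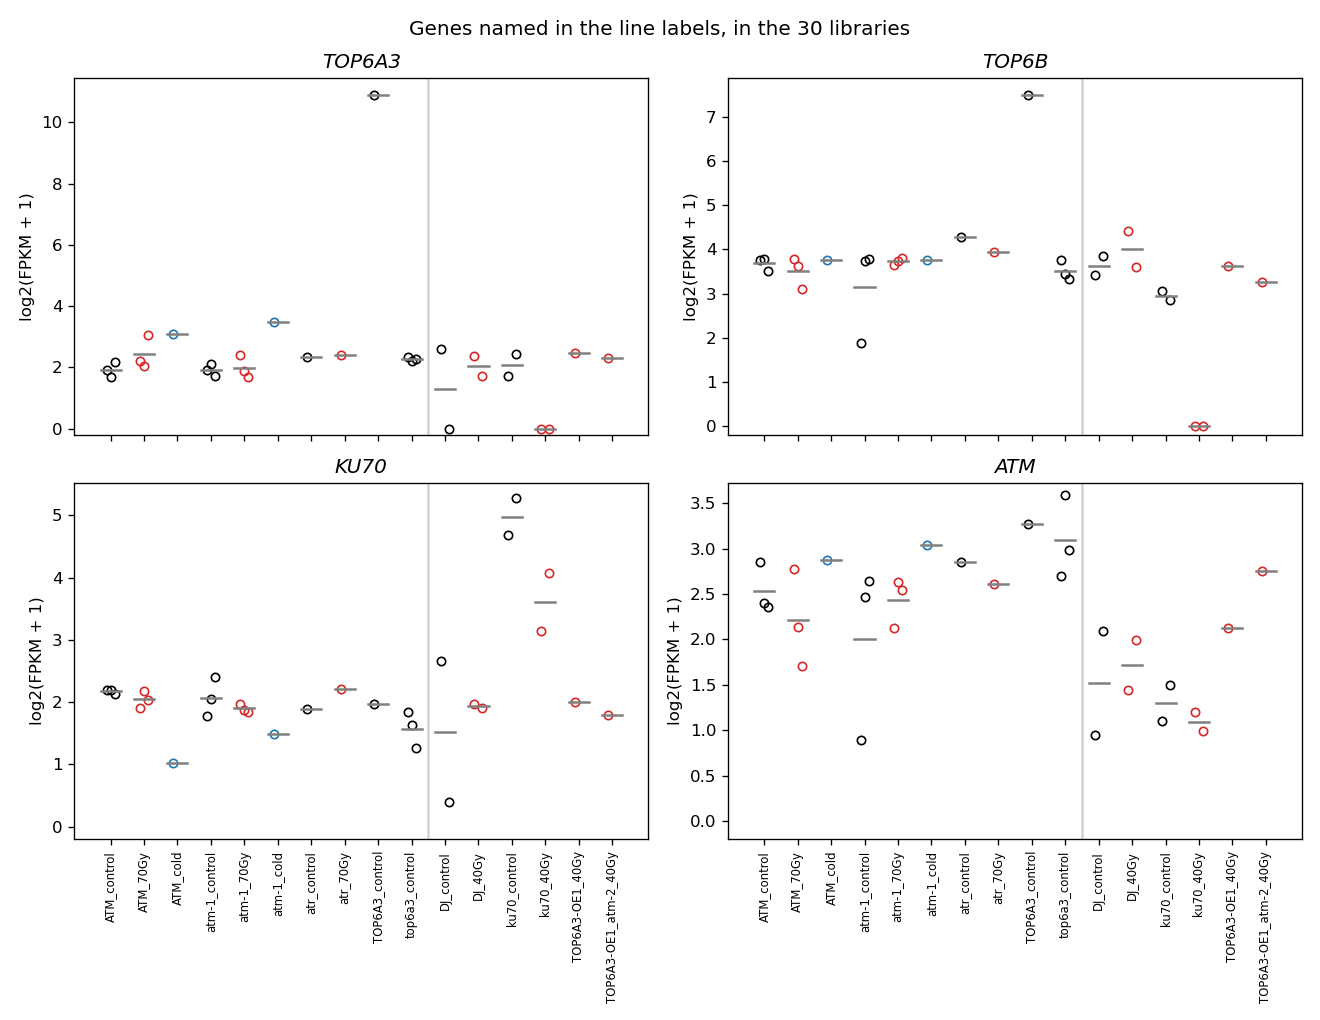
Levels of TOP6A3, TOP6B, KU70 and ATM, log2 of FPKM plus 1 on the y axis, in each of the 30 libraries (circles; black control, red irradiated, blue cold) by group on the x axis, with group means as grey bars and a grey vertical line between the separately normalised tables. TOP6A3 was at 1899 FPKM in the library labelled TOP6A3, KU70 was highest in the libraries labelled ku70, and the libraries labelled ATM and atm-1 overlapped for ATM.

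Irradiation of the ATM line with 70 Gy, which asks what the wild-type allele's leaves do 6 h after DNA damage, raised some transcripts for DNA synthesis and repair, 11 of the 65 DNA damage genes measured. RNRS2 (Os06g0127900, chromosome 6, 1470865 to 1472378), a small subunit of ribonucleotide reductase, which makes deoxynucleotides, rose from 1.65 ± 0.889 to 230 ± 144 FPKM (SD, n = 3 and 3, log2 6.18, limma adjusted p = 0.00165). ST1 (Os06g0257450, chromosome 6, 8230555 to 8232480), another small subunit of that enzyme, rose from 30.2 ± 7.71 to 1605 ± 704 FPKM (log2 5.59, adjusted p = 5.78e-06). RAD51A2 (Os12g0497300, chromosome 12, 18876115 to 18879035), a strand exchange protein of homologous recombination, rose from 0.466 ± 0.302 to 45.6 ± 13.7 FPKM (log2 4.97, adjusted p = 0.000312), and OsPCNA, the sliding clamp of DNA replication, from 11.6 ± 4.37 to 107 ± 40.0 FPKM (log2 3.08, adjusted p = 0.000273). The glutathione S-transferase gene OsGSTU36 had the largest rise, from 0.354 ± 0.112 to 264 ± 197 FPKM (log2 7.03, adjusted p = 0.00248), and KCS19 (Os03g0383600) rose by 3.45 on the log2 scale (adjusted p = 9.84e-07). OsOFP3 fell from 11.2 ± 3.43 to 0.316 ± 0.349 FPKM (log2 -3.21, adjusted p = 0.000284), and the cytochrome c6 gene Os07g0567400 from 55.1 ± 14.4 to 12.9 ± 3.44 FPKM (log2 -2.01). In all, 129 of 24582 genes changed, 106 up and 23 down.

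Of 65 measured genes of DNA damage response and repair, 11 rose and none fell (12 rose when adjusted over the list alone). The list's median change was -0.01 and its mean 0.44, so these differ in sign, and the list ranked above other genes at a preset correlation (adjusted p = 0.000682) but not with an estimated correlation (adjusted p = 0.738). Among 211 cytosolic ribosome genes, 189 were lower and 20 higher, with a median of -0.41 (adjusted p = 7.03e-10, and adjusted p = 0.738 with an estimated correlation), although over all genes 1 rose and none fell, and 6 fell and 1 rose when adjusted over the list alone. None of 20 light harvesting, 35 photosystem, 23 Calvin cycle, 16 chlorophyll synthesis and 17 chloroplast-encoded genes passed the test. None of 36 cold response, 47 secondary wall or 149 defence genes passed it. In 4 further lists 1 gene rose in each: proliferating cells (OsPCNA), epidermis and cuticle (KCS19), heat shock proteins (Os06g0219500, log2 2.98) and antioxidant enzymes (OsGSTU36). Among ABA and drought signalling genes, OsPP2C55 (log2 2.19) and OsKAPP (log2 1.28) rose. The authors' 106 genes were perhaps chosen on these samples, so they are not taken as independent evidence. They had a median of -0.50 with none past the test (adjusted p = 0.0118, and adjusted p = 0.865 with an estimated correlation). The count of 129 was 70 without ATM 70 Gy replicate 1, 72 without replicate 2, and 67, 84 and 77 without ATM control replicates 1, 2 and 3. It was 1656 without both ATM 70 Gy replicate 3 and atm-1 control replicate 1, the libraries with few low-read genes. With a replicate block, which also fitted only the groups compared, the count was lower than 129. Os07g0567400 was no longer called without any 1 of the 6 libraries (adjusted p up to 0.134), nor was OsKAPP without replicate 1 or 2 of either group (adjusted p up to 0.0682).

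**Figure D2:**
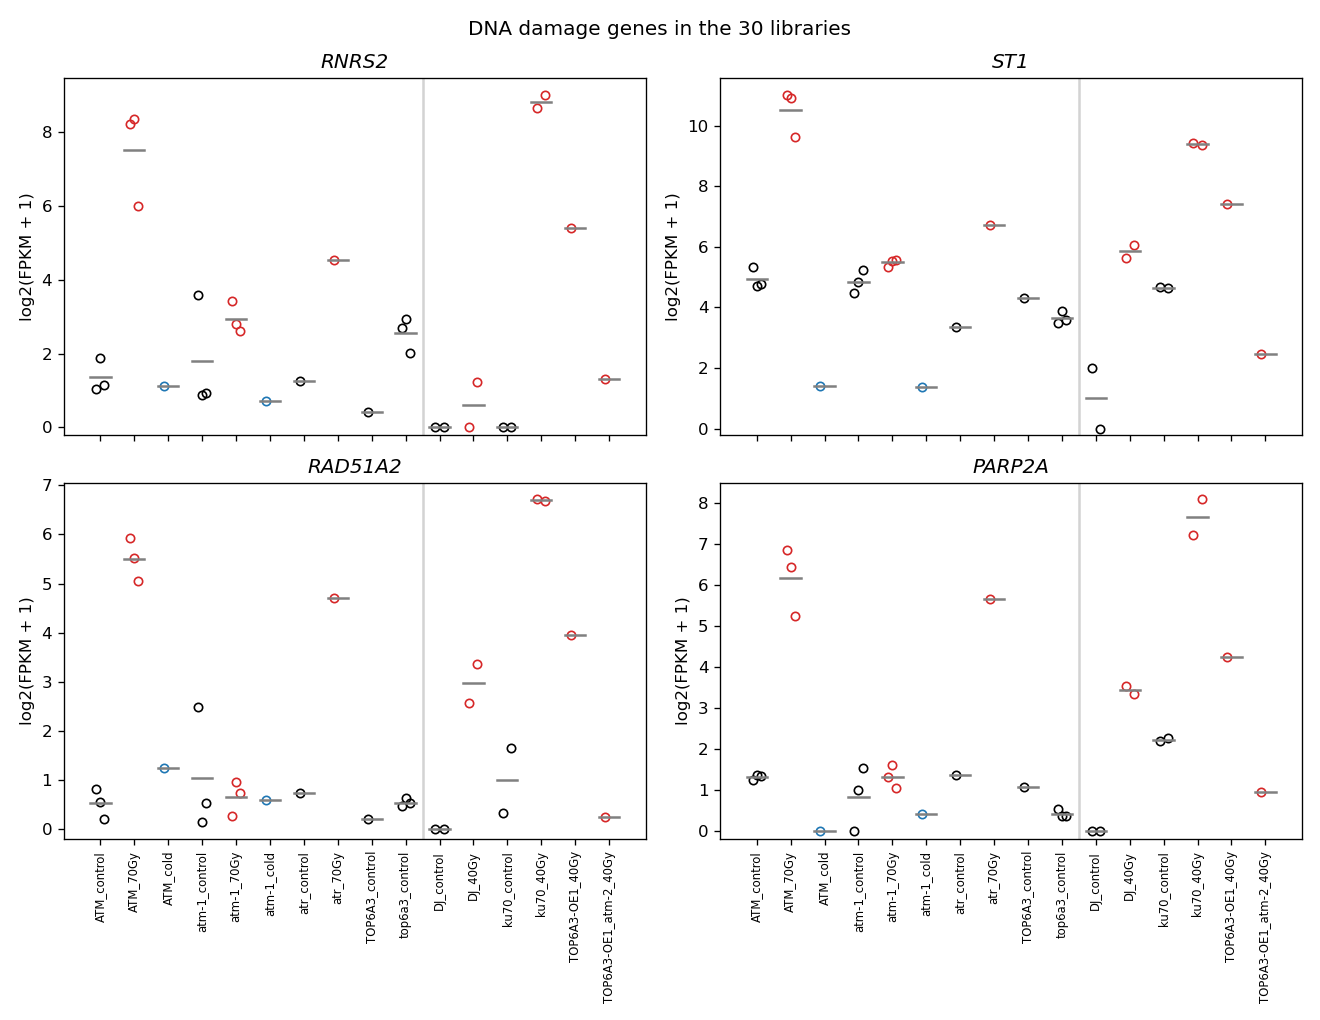
Levels of the DNA damage genes RNRS2, ST1, RAD51A2 and PARP2A, log2 of FPKM plus 1 on the y axis, in each of the 30 libraries (circles; black control, red irradiated, blue cold) by group on the x axis, with group means as grey bars and a grey vertical line between the separately normalised tables. ST1 reached 2067, 1953 and 795 FPKM in ATM at 70 Gy and 39.7, 45.5 and 46.9 FPKM in atm-1 at 70 Gy.

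The lines labelled atm-1 and ATM were compared to ask whether this response needs the ATM kinase. In atm-1, ST1 was at 28.6 ± 7.76 FPKM in the controls and 44.0 ± 3.79 FPKM after 70 Gy (n = 3 and 3), and RAD51A2 was at 4.60, 0.106 and 0.443 FPKM in control replicates 1, 2 and 3 and at 0.211, 0.950 and 0.668 FPKM after 70 Gy. RNRS2 was at 9.80, 5.93 and 5.13 FPKM after 70 Gy and at 11.1, 0.8215 and 0.906 FPKM in those control replicates, the first a library with few low-read genes (log2 1.15, adjusted p = 0.712), and its interaction between lines did not pass (log2 -5.02, adjusted p = 0.139). No gene passed the test in atm-1 at 70 Gy (limma, 0 of 24582; 1877 at an unadjusted p under 0.05; 0 by limma-voom). That count depends on the libraries with few low-read genes and on how libraries are weighted: it was 12 without both of those libraries, 1 without atm-1 70 Gy replicate 2 or atm-1 control replicate 2, and 2649 with library weights. The difference between the lines' responses, tested as an interaction, passed for 41 genes, and in all 41 the change was lower in atm-1: RAD51A2 (log2 -5.36, adjusted p = 0.00711), ST1 (-4.95, adjusted p = 0.000663), ONAC050 (-4.58, adjusted p = 0.000663), KCS19 (-3.51, adjusted p = 4.80e-05) and OsGSTU36 (-7.50, adjusted p = 0.0447). PARP2A (Os01g0351200, chromosome 1, 14047844 to 14054909), a poly(ADP-ribose) polymerase gene, had an interaction of -4.37 (adjusted p = 0.0108), and OsPCNA one of -3.01 (adjusted p = 0.0117), with atm-1 at 15.2 ± 3.50 FPKM in controls and 15.9 ± 2.36 FPKM after 70 Gy. Compared directly at 70 Gy, 81 genes were lower in atm-1 than in ATM and none higher, among them PARP2A (log2 -4.85, adjusted p = 0.000118), ST1 (-5.04, adjusted p = 1.12e-05), RAD51A2 (-4.84, adjusted p = 0.000465) and OsPCNA (-2.62, adjusted p = 0.00104). The count of 81 was 0 with a replicate block fitted to only the groups compared.

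In the interaction, 7 of 65 DNA damage genes passed, all lower in atm-1, and 11 when adjusted over the list alone. The list's median was 0.03 and its mean -0.40, which differ in sign (adjusted p = 8.02e-05, and adjusted p = 0.471 with an estimated correlation). At 70 Gy, 11 of the 65 were lower in atm-1 than in ATM (12 when adjusted over the list alone, with adjusted p = 1.05e-08 for the list, and adjusted p = 0.279 with an estimated correlation). Light harvesting genes had a higher 70 Gy change in atm-1 in 18 of 20 cases, median 0.75, with no gene past the test (adjusted p = 0.00771, and adjusted p of 0.471 or more with an estimated correlation for every list of this comparison). Within atm-1, light harvesting genes had a median of 0.96 at 70 Gy, with no gene called over all genes and 7 higher when adjusted over the list alone (adjusted p = 1.16e-06, and adjusted p = 0.308 with an estimated correlation). Photosystem (0.85), Calvin cycle (0.93) and chlorophyll synthesis (1.19) genes also had positive median interactions, none with a gene past the test. So did the authors' 106 genes (1.08), perhaps chosen on these samples and so not taken as independent evidence. The interaction count of 41 was 23 without ATM 70 Gy replicate 2, 24 without ATM control replicate 2, and 17, 25 and 16 without atm-1 70 Gy replicates 1, 2 and 3. It was 98 without both libraries with few low-read genes, 8 by limma-voom and 0 with a replicate block fitted to only the groups compared. RAD51A2 had an interaction of -4.65 without atm-1 control replicate 1 (adjusted p = 0.000488) and was not called by limma-voom (adjusted p = 0.198), with a pseudocount of 0.1 (0.137) or with a replicate block (0.0859). OsPCNA was no longer called in the interaction without atm-1 70 Gy replicate 1 or 3 (adjusted p up to 0.0509), nor PARP2A without atm-1 70 Gy replicate 3 (0.0505). OsGSTU36 kept its call only without ATM 70 Gy replicate 3 or without atm-1 control replicate 1 or 3 (adjusted p up to 0.158 without the other 9 libraries).

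Without treatment, atm-1 and ATM leaves differed in no gene past the test (limma, 0 of 24582; 1330 at an unadjusted p under 0.05; 0 by limma-voom). As groups, the photosystem genes had a median of -0.61 in atm-1 (adjusted p = 0.000492, and adjusted p = 0.485 with an estimated correlation). The authors' 106 genes were perhaps chosen on these samples, so they are not taken as independent evidence. They had a median of -0.71, with 91 lower and 15 higher (adjusted p = 1.18e-08, and adjusted p = 0.485 with an estimated correlation). No member of any list passed, over all genes or adjusted over the list alone. The count was 1 without ATM control replicate 1, 2 without atm-1 control replicate 2 and 1 without atm-1 control replicate 3, and atm-1 control replicate 1, a library with few low-read genes, stands in this group.

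The line labelled atr had 1 library per condition, so its values carry no test. After 70 Gy, 40 of 57 measured genes of DNA damage response and repair were higher, 8 of these by 1 or more on the log2 scale, and 17 lower (median 0.19, at percentile 98.85 of 10000 random lists matched on expression). Of the 4 DNA damage genes followed in every line, RAD51A2 was at 25.3 FPKM against 0.662 FPKM in the control, PARP2A at 49.5 against 1.58 FPKM, RNRS2 at 22.4 against 1.41 FPKM and ST1 at 106 against 9.17 FPKM. Of the 106 genes that rose in ATM at 70 Gy, 96 were measured in atr and 85 were higher after 70 Gy (median log2 difference 1.31, above all random lists). All 20 light harvesting genes were lower (median -2.78, below all random lists), as were 30 of 33 photosystem genes (-2.37), 19 of 21 Calvin cycle genes (-2.41) and 13 of 15 chlorophyll synthesis genes. CP29, an antenna protein of photosystem II, was at 86.1 FPKM after 70 Gy and 1133 FPKM without it, and PSBO, of the oxygen evolving complex, at 150 and 1657 FPKM. Of the authors' 106 genes (perhaps chosen on these samples, so not taken as independent evidence) 99 were lower (median -2.13). The largest differences upward were OsLTP2.9, a lipid transfer protein gene (682 against 0.473 FPKM), and OsFWL7 (162 FPKM against a control listed at 0); the largest downward was a chitinase 4 gene (0.697 against 64.4 FPKM). In the control library, genes with 1 to 10 reads made up 16.8% of detected genes, and in the 70 Gy library 10.8%.

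**Figure D3:**
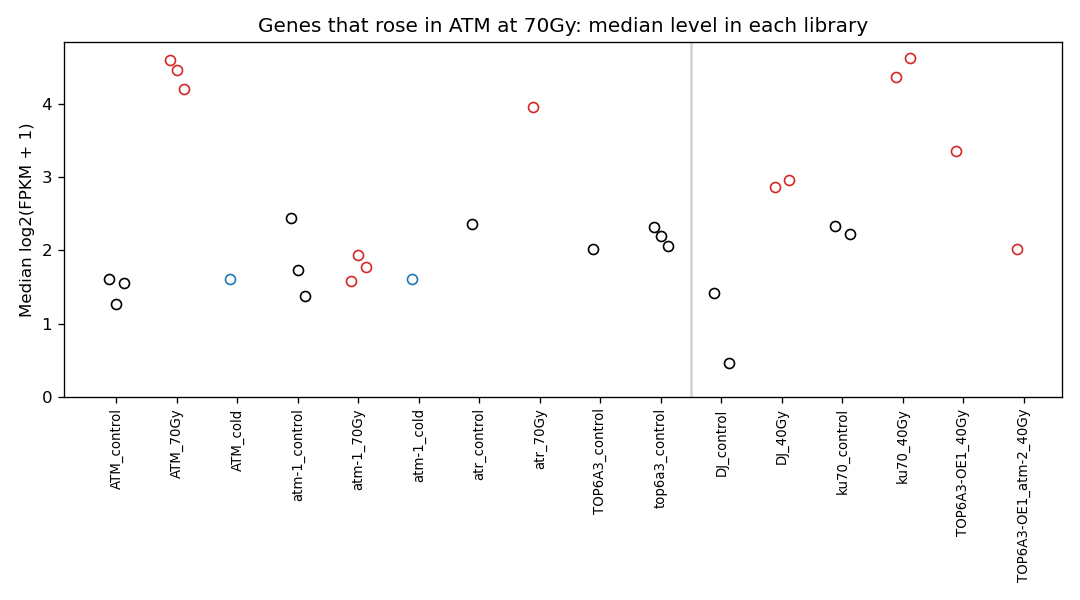
Median level of the genes that rose in ATM at 70 Gy, log2 of FPKM plus 1 on the y axis, in each of the 30 libraries (circles; black control, red irradiated, blue cold) by group on the x axis, over 106 genes left of the grey vertical line and 103 genes right of it, where the separately normalised table begins. The medians were 4.20 to 4.61 in ATM at 70 Gy, where the genes were chosen, 1.58 to 1.93 in atm-1 at 70 Gy, and 3.37 in TOP6A3-OE1 against 2.01 in TOP6A3-OE1_atm-2 at 40 Gy.

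In the wild type DJ, the comparison of 40 Gy with no irradiation asked how leaves respond in 6 h to the lower dose. As lists, transcripts of the photosystems and the Calvin cycle were lower and transcripts of the cytosolic ribosome higher. RBCS, the small subunit of Rubisco, fell from 558 ± 16.4 to 155 ± 13.4 FPKM (SD, n = 2 and 2, log2 -1.85, adjusted p = 0.0156), and PsbP, of the oxygen evolving complex, from 1309 ± 76.0 to 329 ± 63.4 FPKM (adjusted p = 0.0357). RPS20, a ribosomal protein gene, rose from 66.3 ± 0.221 to 216 ± 8.02 FPKM (log2 1.69, adjusted p = 0.0168). ST1 rose (log2 4.86, adjusted p = 0.0496), from 3.00 and 0 FPKM to 48.9 and 66.2 FPKM. PARP2A, listed at 0 in both controls, rose to 10.6 and 9.19 FPKM (adjusted p = 0.0371). OsGSTU36 and the chitinase 4 gene Os04g0493600, also listed at 0 in both controls, rose to 6.86 ± 2.71 and 20.04 ± 0.397 FPKM. RNRS2 was at 0 and 0 FPKM without and 0 and 1.34 FPKM with irradiation. Genes with 1 to 10 reads made up 2.57% and 1.28% of detected genes in DJ control replicates 1 and 2. Whether values of 0 there were missed transcripts was not tested, so rises from 0 are less sure. In all, 237 of 23063 genes changed, 111 up and 126 down.

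Of 36 photosystem genes, 4 fell and none rose, and 18 fell and 1 rose when adjusted over the list alone. The median was -1.41 (adjusted p = 2.37e-13, and adjusted p = 0.0156 with an estimated correlation). Of 24 Calvin cycle genes 2 fell, and 11 when adjusted over the list alone. The median was -1.03 (adjusted p = 1.17e-08, and adjusted p = 0.0231 with an estimated correlation). Of 20 light harvesting genes 1 fell and 1 rose, and 14 fell and 1 rose when adjusted over the list alone. The median was -1.59 (adjusted p = 1.17e-08, and adjusted p = 0.0687 with an estimated correlation). Of 210 ribosome genes 10 rose, and 85 rose and 1 fell when adjusted over the list alone. The median was 1.00 (adjusted p = 5.20e-35, and adjusted p = 0.0156 with an estimated correlation). Of 58 DNA damage genes 3 rose, and 4 when adjusted over the list alone (median 0.10, adjusted p = 0.0798). The authors' 106 genes were perhaps chosen on these samples, so they are not taken as independent evidence. Of them 6 fell and none rose, and 48 and 2 when adjusted over the list alone. The median was -1.11 (adjusted p = 1.51e-20, and adjusted p = 0.0156 with an estimated correlation). The genes that had risen in ATM at 70 Gy rose here as a set (median 1.16, 76 of 95 higher, 10 called up, and adjusted p = 0.00646 with an estimated correlation). The count of 237 was 0 when only the groups compared were fitted, 0 with a replicate block, 1 with robust moderation and 77 by limma-voom. RBCS and RPS20 lost their calls in the first 3 of these (adjusted p up to 0.301 for each). Of the 29 named genes, 23 lost their call when some library was left out, while RBCS and RPS20 did not. ST1 lost it without either irradiated library (adjusted p up to 0.146), PARP2A and OsGSTU36 without any 1 of the 4 libraries (up to 0.112 and 0.114), and PsbP without any but DJ 40 Gy replicate 2 (up to 0.0859).

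The libraries labelled ku70 were compared with DJ without treatment, which asks what differed before irradiation. OsXTH10, a cell wall xyloglucan enzyme gene, was lower in ku70 (1.26 ± 0.370 against 223 ± 85.3 FPKM; SD, n = 2 and 2, log2 -6.58, adjusted p = 0.0103), as were OsGELP83 (0.599 ± 0.847 against 154 ± 14.5 FPKM, log2 -6.70, adjusted p = 0.0256), the peroxidase gene prx65 (log2 -4.48) and the lipid transfer gene OsLTP1.17 (log2 -2.33). RBBI2-2, a Bowman-Birk protease inhibitor gene, was higher (570 ± 48.3 against 47.9 ± 13.1 FPKM, log2 3.57, adjusted p = 0.0448), as was its neighbour in name RBBI2-1 (log2 3.55). In all 143 genes differed, 91 higher and 52 lower. No photosystem gene passed over all genes, and 14 of 36 were higher when adjusted over the list alone (median 0.87, adjusted p = 1.46e-10, and adjusted p = 0.0475 with an estimated correlation). Light harvesting (0.64) and Calvin cycle (0.69) genes had positive medians with none called (adjusted p = 0.000186 and 0.000396, and adjusted p = 0.198 and 0.127 with an estimated correlation). Of 37 epidermis and cuticle genes, 2 were lower, and 3 when adjusted over the list alone. The median was -0.31 (adjusted p = 0.0101, and adjusted p = 0.606 with an estimated correlation). The count of 143 was 241 without DJ control replicate 2 and 215 without ku70 control replicate 2, and it was 0 by limma-voom, 0 when only the groups compared were fitted and 2 with robust moderation. OsGELP83, RBBI2-2 and OsLTP1.17 were no longer called without any 1 of the 4 libraries (adjusted p up to 0.113, 0.227 and 0.234), nor RBBI2-1 without any but DJ control replicate 1 (0.131), nor prx65 without either DJ control or ku70 control replicate 2 (0.0902).

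In the libraries labelled ku70, 40 Gy was followed by lower levels of photosystem and Calvin cycle transcripts as lists and by higher levels of some DNA damage transcripts. Of 58 DNA damage genes 6 rose and 3 fell, and their list did not pass with an estimated correlation (adjusted p = 0.0726). All 3 that fell had no read in either irradiated library. RNRS2 was listed at 0 in both controls and at 403 and 515 FPKM after 40 Gy (adjusted p = 0.00422). RAD51A2 rose from 1.21 ± 1.34 to 103 ± 2.09 FPKM (SD, n = 2 and 2, log2 5.70, adjusted p = 0.00910), PARP2A from 3.69 ± 0.180 to 209 ± 86.2 FPKM (log2 5.42, adjusted p = 0.00553), OsPCNA from 12.8 ± 1.46 to 157 ± 9.52 FPKM (log2 3.52) and OsGSTU36 from 4.39 ± 1.04 to 343 ± 15.1 FPKM (log2 6.01). PSAH, a subunit of photosystem I, fell from 10770 ± 372 to 576 ± 74.9 FPKM (log2 -4.23, adjusted p = 0.00378), RbcS3, a Rubisco small subunit, from 7791 ± 295 to 634 ± 203 FPKM (log2 -3.66, adjusted p = 0.00744) and OsGLK1, a transcription factor of chloroplast development, from 292 ± 26.7 to 45.1 ± 5.98 FPKM (log2 -2.67). In all 2287 genes changed, 654 up and 1633 down, beside a median shift of all genes of -0.29.

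Of 36 photosystem genes 26 fell, and 28 fell and 1 rose when adjusted over the list alone. The median was -2.95 (adjusted p = 1.47e-14, and adjusted p = 0.0214 with an estimated correlation). Of 24 Calvin cycle genes 16 fell, and 18 fell and 1 rose when adjusted over the list alone. The median was -2.52 (adjusted p = 1.35e-09, and adjusted p = 0.0214 with an estimated correlation). Of 20 light harvesting genes 12 fell, and 16 when adjusted over the list alone. The median was -2.74 (adjusted p = 2.74e-09, and adjusted p = 0.0566 with an estimated correlation). Of 210 ribosome genes 44 rose and 3 fell, and 80 and 6 when adjusted over the list alone. The median was 0.89 (adjusted p = 1.32e-22, and adjusted p = 0.0214 with an estimated correlation). Of the 58 DNA damage genes 7 rose and 3 fell when adjusted over the list alone. The median was 0.11 (adjusted p = 0.0195 at the preset correlation). The authors' 106 genes were perhaps chosen on these samples, so they are not taken as independent evidence. Of them 62 fell, and 74 fell and 1 rose when adjusted over the list alone. The median was -2.60 (adjusted p = 3.03e-21, and adjusted p = 0.0214 with an estimated correlation). The genes that had risen in ATM at 70 Gy had a median of 1.79, with 32 called up and 1 down (adjusted p = 0.00646 with an estimated correlation). This set was also higher in ku70 than in DJ without treatment (median 0.57, 75 of 95 higher, adjusted p = 0.0222 with an estimated correlation), with 1 gene called. Its median level was low and differed between DJ control replicates 1 and 2 (1.67 and 0.382 FPKM), against 4.04 and 3.65 FPKM in the ku70 controls. In both irradiated libraries many transcripts had no read. Of genes at 5 FPKM or more in every other library of this table, 263 of 7203 and 215 of 7082 had none, against 30 of 6822 or fewer in each other library. Of the 1633 genes called lower, 813 had no read in either irradiated library, and of the 26 photosystem genes called lower, 24 had 10 or more reads in both. All 3 DNA damage genes and all 3 ribosome genes called lower had no read in either. The count of 2287 was 484 without ku70 control replicate 1 and 443 without replicate 2, without either of which RbcS3 and OsGLK1 were no longer called (adjusted p up to 0.0575 and 0.0873). Of the 51 named genes, 39 lost their call when some library was left out.

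The interaction between line and 40 Gy asks whether ku70 and DJ leaves responded differently. It passed for 266 genes, 90 with a more positive and 176 with a more negative change in ku70, beside a median of all genes of -0.27. Of the 176, 155 had no read in either ku70 40 Gy library, and of the 90, 58 had none in either ku70 control. The pair of ku70 40 Gy libraries correlated at Pearson's r = 0.7504 across genes, close to their 0.739 to 0.7445 with the DJ 40 Gy libraries, while the ku70 controls correlated at 0.937. RNRS2 had an interaction of 8.22 (adjusted p = 0.0213), and OsLTP2.6, a lipid transfer protein gene, one of 8.09 (adjusted p = 0.0212). Os11g0645400, described as a dirigent protein, was listed at 0 in both ku70 controls and at 40.6 ± 16.1 FPKM after 40 Gy (SD, n = 2). In DJ it was at 17.7 ± 15.7 FPKM before and listed at 0 after 40 Gy, giving an interaction of 9.24 (adjusted p = 0.0342). RBCS had an interaction of -1.76 (adjusted p = 0.0291), with ku70 at 568 ± 7.74 FPKM before and 45.7 ± 1.04 FPKM after irradiation. Of 36 photosystem genes none passed over all genes, and 22 had a more negative and 1 a more positive change in ku70 when adjusted over the list alone (median -1.64, adjusted p = 2.45e-09, and adjusted p = 0.0639 with an estimated correlation). Calvin cycle genes had a median of -1.43, with 1 of 24 past the test (8 when adjusted over the list alone, with adjusted p = 3.00e-05 for the list, and adjusted p = 0.0767 with an estimated correlation), and DNA damage genes a median of -0.21 and a mean of 0.20, which differ in sign, with 1 past the test (adjusted p = 0.308). The genes that had risen in ATM at 70 Gy had a median of 0.52, with 65 of 95 more positive in ku70 and 1 called (adjusted p = 0.0251 with an estimated correlation). That value rests in part on the DJ controls, in which the set's median level was 1.67 and 0.382 FPKM. The count of 266 was 420 without DJ 40 Gy replicate 2, 557 by limma-voom, 11 when only the groups compared were fitted, 6 with robust moderation and 0 with a replicate block. RNRS2 was no longer called without ku70 control replicate 1 or 2 (adjusted p up to 0.0533), nor OsLTP2.6 without ku70 control replicate 1 (0.0509). RBCS lost its call without DJ control replicate 1 or any 1 ku70 library (adjusted p up to 0.0698), and Os11g0645400 without any 1 library except the DJ controls (0.104).

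The libraries labelled TOP6A3-OE1 address whether extra TOP6A3 changes leaves after 40 Gy, and whether that needs ATM, although TOP6A3 itself stood at 4.49 FPKM in the first of them. Against DJ at 40 Gy, the peroxidase gene POX8.1 was at 621 FPKM in TOP6A3-OE1 and listed at 0 in both DJ libraries, and the jacalin-related lectin gene OsJRL was higher by 8.99 on the log2 scale. RNRS2 was higher (41.4 FPKM, log2 4.79, adjusted p = 0.0141), and PSBS2, a photoprotection protein gene of photosystem II, was lower (2.71 against 379 ± 72.9 FPKM; SD, n = 2, log2 -6.67, adjusted p = 0.00129). In all 1148 genes differed, 759 higher and 389 lower, with 1 TOP6A3-OE1 library. The count was 151 when only the groups compared were fitted, 579 with robust moderation, 598 with a filter of 5 FPKM, 379 with a mean of 20 FPKM or more, 839 by limma-voom and 2457 with no filter. The lines also differed in which genes had reads: of 7062 genes at 5 FPKM or more in every DJ and ku70 library, 127 had no read in either TOP6A3-OE1 library, and of 11410 genes at that level in both TOP6A3-OE1 libraries, 135 had none in any DJ or ku70 library. The 1148 differences are therefore not separated from differences between the backgrounds of the lines. Genes with 1 to 10 reads made up 1.22% and 2.45% of detected genes in DJ 40 Gy replicates 1 and 2, against 5.80% in TOP6A3-OE1. Whether values of 0 in DJ were missed transcripts was not tested, so genes higher from 0, such as POX8.1, are less sure. Of 27 cold response genes 4 were higher and 1 lower, and 7 and 1 when adjusted over the list alone (median 1.17, adjusted p = 0.0118). Of 37 epidermis genes 3 were higher and 1 lower, and 5 and 1 when adjusted over the list alone (median 1.41, adjusted p = 0.0183). Of 72 genes of proliferating cells 1 was higher and 3 lower, and 1 and 4 when adjusted over the list alone (median -0.67, adjusted p = 0.00127). With an estimated correlation every list had an adjusted p of 0.638 or more. Among DNA damage genes, 2 of 58 were higher and 1 lower. POX8.1 was no longer called without either DJ 40 Gy library (adjusted p up to 0.114), nor OsJRL without DJ 40 Gy replicate 1 (0.0843).

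TOP6A3-OE1_atm-2 and TOP6A3-OE1 at 40 Gy had 1 library each, so no test was made. Of 54 measured genes of DNA damage response and repair, 32 were lower and 22 higher with atm-2 (median -0.19, at percentile 10.46 of 10000 random lists), so the list as a whole lay among the random lists. The 4 DNA damage genes followed in every line were lower: RNRS2 was at 1.49 against 41.4 FPKM, ST1 at 4.51 against 169 FPKM, RAD51A2 at 0.198 against 14.4 FPKM and PARP2A at 0.944 against 18.1 FPKM. Of the genes that rose in ATM at 70 Gy, 75 of 87 were lower (median -1.33, below all random lists). All 19 light harvesting genes were higher (median 2.02, above all random lists), among them Lhcb1.1 at 1369 against 17.5 FPKM. Also higher were 30 of 33 photosystem genes (1.58), 21 of 23 Calvin cycle genes (1.76) and 94 of 105 of the authors' genes (1.70). The authors' genes were perhaps chosen on these samples, so they are not taken as independent evidence. Lower were 192 of 209 ribosome genes (-0.64) and 31 of 36 epidermis genes (-1.42), both below all random lists. Genes with 1 to 10 reads made up 20.8% of detected genes in TOP6A3-OE1_atm-2 and 5.80% in TOP6A3-OE1.

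**Figure D4:**
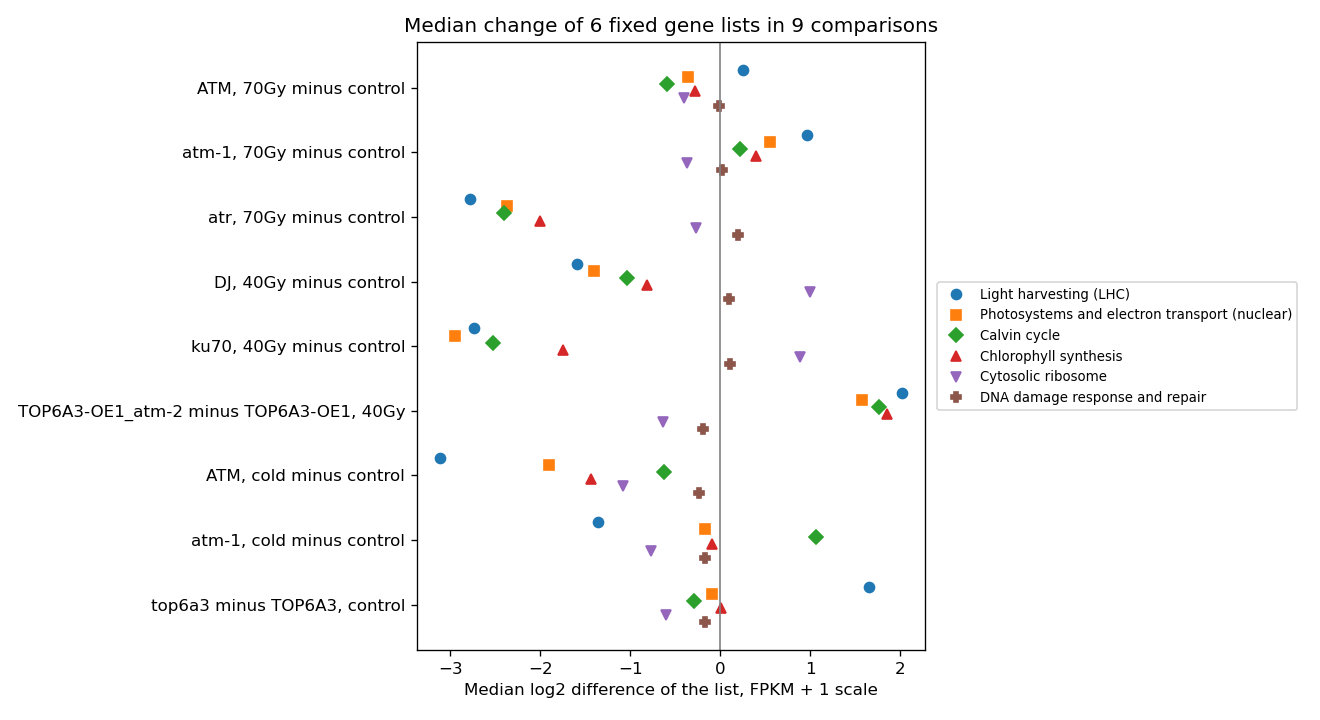
Median log2 difference (FPKM plus 1 scale, x axis) of 6 fixed gene lists in 9 comparisons (y axis), each marker being the median over the measured members of 1 list. Light harvesting genes had medians of -2.78 in atr at 70 Gy, -2.74 in ku70 at 40 Gy and -3.11 in ATM in the cold, and of 0.96 in atm-1 at 70 Gy and 2.02 in TOP6A3-OE1_atm-2 minus TOP6A3-OE1.

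Keeping ATM leaves at 4 °C for 24 h asked how chilling changes leaf transcripts. Some genes of cold response (8 of 36) and defence (24 of 149) rose and some of the light harvesting antenna (12 of 20) fell, though none of these lists passed with an estimated correlation (adjusted p = 0.682, 0.452 and 0.1002). The largest rise was in a fragment of large subunit rRNA, 1128 FPKM in the lone cold library against 3.04 ± 1.82 FPKM in the controls (SD, n = 3, log2 8.22, adjusted p = 0.0194). A pair of 5.8S rRNA genes, at 781 and 578 FPKM against 4.41 ± 1.22 and 3.05 ± 0.803 FPKM, were also among the 5 largest rises, and whether RNA quality or rRNA removal in that library set them was not tested. OsDREB1B, a transcription factor of cold response, stood at 4005 FPKM against 35.7 ± 28.9 FPKM in the controls (log2 7.13, adjusted p = 7.46e-05), OsPAL1, a phenylalanine ammonia-lyase gene, at 3345 against 19.0 ± 7.33 FPKM (log2 7.46, adjusted p = 2.20e-05), and OsABA8OX1, for breakdown of abscisic acid, at 156 against 1.43 ± 0.310 FPKM (log2 6.02). CAB1R and CAB2R, chlorophyll a/b binding proteins, fell from 2628 ± 796 to 19.4 FPKM (log2 -6.97, adjusted p = 1.68e-05) and from 450 ± 76.9 to 4.26 FPKM (log2 -6.41), and PSBS2 from 263 ± 161 to 0.703 FPKM (log2 -7.04). ST1 also fell, to 1.62 FPKM (log2 -3.54). In all 3497 genes changed, 1815 up and 1682 down. With 1 library in the cold arm, here and in atm-1, the p-values rest on the spread within other groups and do not measure variation between cold libraries.

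Of 20 light harvesting genes 12 fell and none rose in the cold, and 14 and 1 when adjusted over the list alone. The median was -3.11 (adjusted p = 5.81e-11, and adjusted p = 0.1002 with an estimated correlation). Of 35 photosystem genes 10 fell and 2 rose, and 17 and 2 when adjusted over the list alone. The median was -1.90 (adjusted p = 2.77e-05, and adjusted p = 0.332 with an estimated correlation). PsaD of photosystem I was among those that fell (log2 -4.45). Of 36 cold response genes 8 rose, and 9 when adjusted over the list alone. The median was 0.21 (adjusted p = 0.0275, and adjusted p = 0.682 with an estimated correlation). Of 149 defence genes 24 rose and 3 fell, and 26 and 3 when adjusted over the list alone. The median was 0.60 (adjusted p = 0.000237, and adjusted p = 0.452 with an estimated correlation). WRKY71 led these (5516 against 164 ± 86.4 FPKM). Of 211 ribosome genes 71 fell and 3 rose, and 123 and 4 when adjusted over the list alone. The median was -1.08 (adjusted p = 1.02e-17, and adjusted p = 0.395 with an estimated correlation). Of 77 genes of proliferating cells 17 fell and 3 rose, and 24 and 4 when adjusted over the list alone. The median was -0.58 (adjusted p = 0.000280, and adjusted p = 0.332 with an estimated correlation). The authors' 106 genes were perhaps chosen on these samples, so they are not taken as independent evidence. Of them 37 fell, and 50 fell and 2 rose when adjusted over the list alone. The median was -1.73 (adjusted p = 1.21e-14, and adjusted p = 0.332 with an estimated correlation). Without both libraries with few low-read genes, neither of them in this comparison, the count was 8736.

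In atm-1 the largest rise in the cold was in Os12g0548401, described as a subtilisin-chymotrypsin inhibitor (637 FPKM, listed at 0 in all 3 controls, log2 9.32, adjusted p = 0.00153), and none of the 5 largest rises was among the 5 largest in ATM. Of the genes given above for ATM, OsDREB1B stood at 6003 against 48.4 ± 14.1 FPKM (SD, n = 3, log2 6.96), WRKY71 was higher by 5.08 on the log2 scale, CAB1R fell from 2217 ± 853 to 35.7 FPKM (log2 -5.85) and PSBS2 by 6.23 on the log2 scale. The peroxidase gene prx127 rose (log2 7.12, adjusted p = 1.92e-07), and in all 3832 genes changed, 2326 up and 1506 down. Of 20 light harvesting genes 9 fell, and 10 when adjusted over the list alone. The median was -1.35 (adjusted p = 3.45e-05, and adjusted p = 0.358 with an estimated correlation). Of 35 photosystem genes 3 fell and 1 rose (median -0.16, adjusted p = 0.146). Of 23 Calvin cycle genes 4 rose, and 5 when adjusted over the list alone. The median was 1.07 (adjusted p = 0.0197, and adjusted p = 0.552 with an estimated correlation). Of 36 cold response genes 10 rose, and 12 when adjusted over the list alone. The median was 0.29 (adjusted p = 0.0116, and adjusted p = 0.561 with an estimated correlation). Of 211 ribosome genes 43 fell, and 52 fell and 1 rose when adjusted over the list alone. The median was -0.76 (adjusted p = 1.58e-12, and adjusted p = 0.552 with an estimated correlation). The count of 3832 was 6108 without atm-1 control replicate 1, a library with few low-read genes, and 0 when only the groups compared were fitted.

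Whether the cold response differs between atm-1 and ATM was examined as an interaction with 1 cold library per line. It passed for 40 genes, 31 more positive and 9 more negative in atm-1, but for 0 by limma-voom, 0 when only the groups compared were fitted and 3 with a filter of 5 FPKM. The genes with the largest values were at or near 0 in every control, so their small spread comes from libraries without the transcript, and they are given as differences between single cold libraries, without p-values. They were Os03g0286500, described as an RNA-binding protein (27.9 FPKM in the atm-1 and 1.95 FPKM in the ATM cold library, log2 interaction 3.37), OsSCP5, a serine carboxypeptidase gene (45.2 and 3.64 FPKM, 3.32), and Os03g0109350 (21.0 and 1.53 FPKM, 3.12). Light harvesting genes had a median of 1.57, with 18 of 20 higher and none past the test (adjusted p = 5.43e-06, and adjusted p = 0.280 with an estimated correlation). Calvin cycle genes had one of 1.59 (adjusted p = 7.24e-06, and adjusted p = 0.280 with an estimated correlation) and photosystem genes one of 1.43 (adjusted p = 0.000299, and adjusted p = 0.435 with an estimated correlation), with none past the test. Among the largest differences the other way were small non-coding RNAs listed at 0 in every control: U11, at 0.878 FPKM in the atm-1 and 12.5 FPKM in the ATM cold library (log2 interaction -2.85), and tRNA-Gln, at 6.09 and 31.0 FPKM (-2.17).

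The 3 libraries labelled top6a3 were compared with the library labelled TOP6A3 to ask what loss of a TOP6 subunit does in untreated leaves. Some transcripts of the light harvesting antenna (10 of 20, with 2 lower) and of the epidermis and cuticle (17 of 48, with 1 lower) were higher in top6a3, though neither list passed with an estimated correlation (adjusted p = 0.465 and 0.103). GLP8-12, a germin-like protein gene, was at 2265 ± 389 FPKM (SD, n = 3) against 0.0654 FPKM in the library labelled TOP6A3 (log2 11.04, adjusted p = 1.53e-05). CAB2R was at 5609 ± 1276 against 9.44 FPKM (log2 9.04, adjusted p = 0.000115) and Lhcb1.1 at 2015 ± 1523 against 1.48 FPKM (log2 9.39, adjusted p = 0.00234). OsPorA, an enzyme of chlorophyll synthesis, was at 339 ± 34.3 against 1.18 FPKM (log2 7.28) and PsbR, of photosystem II, at 1242 ± 38.2 FPKM against a library listed at 0. OsTOP6A3 itself was lower in top6a3 than in the library labelled TOP6A3 (log2 -8.63, adjusted p = 2.35e-08), and OsPCL1, a clock gene, was at 1.38 ± 0.554 against 181 FPKM (log2 -6.28). In all 3166 genes differed, 2010 higher and 1156 lower.

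Of 20 light harvesting genes 10 were higher and 2 lower in top6a3, and 11 and 3 when adjusted over the list alone. The median was 1.65 (adjusted p = 0.00741, and adjusted p = 0.465 with an estimated correlation). Of 48 epidermis and cuticle genes 17 were higher and 1 lower, and 24 and 1 when adjusted over the list alone. The median was 2.31 (adjusted p = 1.77e-09, and adjusted p = 0.103 with an estimated correlation). Of 47 secondary wall genes 9 were higher and 1 lower, and 11 and 2 when adjusted over the list alone. The median was 0.76 (adjusted p = 0.0337, and adjusted p = 0.199 with an estimated correlation). Of 149 defence genes 22 were higher and 2 lower, and 23 and 2 when adjusted over the list alone. The median was 0.82 (adjusted p = 0.000111, and adjusted p = 0.451 with an estimated correlation). The chitinase gene Oschib2 was among them (log2 7.76). Of 162 antioxidant genes 27 were higher and 3 lower, and 36 and 5 when adjusted over the list alone. The median was 0.66 (adjusted p = 0.000528, and adjusted p = 0.132 with an estimated correlation). Of 35 photosystem genes 2 were higher and 3 lower (median -0.09), and of 65 DNA damage genes 1 was higher and 2 were lower. The authors' 106 genes were perhaps chosen on these samples, so they are not taken as independent evidence. Of them 15 were higher and 7 lower (16 and 10 when adjusted over the list alone), with a median of -0.46 and a mean of 0.17, which differ in sign (adjusted p = 0.504). With the 3 ATM controls as wild type in place of the lone library, 7829 genes were called and 2149 of the 3166 kept their call and direction. OsTOP6A3 was then at 0.35, and light harvesting genes had 5 higher and 4 lower with a median of 0.38.

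The series title joins chilling, photosynthesis genes and the TOP6 complex, so the top6a3 differences were set beside the cold changes of the ATM line, with which they share no library. Of the genes tested, 236 were lower in both, where 79.1 would be shared if the calls were independent, and 182 were higher in both, where 148 would be. Opposite calls numbered 63 (higher in top6a3, lower in the cold; 138 if independent) and 36 (lower in top6a3, higher in the cold; 85.4 if independent). Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.207 and Spearman's rho 0.256. Of 20 light harvesting genes, 9 were called higher in top6a3 and lower in the cold, 1 was called lower in both and none higher in both. Their median of 1.65 in top6a3, against -3.11 in the cold, rests on the lone library labelled TOP6A3, and with the ATM controls as wild type it was 0.38, with 5 higher and 4 lower.

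The authors' deposited table of genes for DJ at 40 Gy lists 770 genes, 343 higher and 427 lower, and all 770 had the same sign here, with 124 called here. In the authors' deposited table of gene ontology terms, photosynthesis held 17 of these genes, 16 of them lower (adjusted p = 6.33e-08), and peptide biosynthesis 30, 29 of them higher (adjusted p = 0.00222). For the authors' 106 genes, the median log2 fold change in the authors' deposited table and here was -1.09 and -1.11 in DJ at 40 Gy, -2.68 and -2.60 in ku70 at 40 Gy, -0.42 and -0.50 in ATM at 70 Gy, 0.18 and 0.48 in atm-1 at 70 Gy, and -1.69 and -1.65 in TOP6A3-OE1 minus TOP6A3-OE1_atm-2. Gene by gene, the sign in the authors' deposited table was that found here for 94 of 106 genes in ATM at 70 Gy, for 66 of 106 in atm-1 at 70 Gy and for 86 of 106 in TOP6A3-OE1 minus TOP6A3-OE1_atm-2 (Spearman's rho across genes 0.874, -0.153 and -0.094). The authors' group means were set beside the recovered reads of all 16 groups (log2 scale). Of 17 such columns, 13 correlated best with their own group. The authors' ATM 70 Gy means correlated slightly better with atm-1 70 Gy (Pearson's r across genes 0.994) than with all 3 ATM 70 Gy libraries (0.991), but differed from the mean of ATM 70 Gy replicates 1 and 2 by an SD of only 0.0061, which leaves out replicate 3, a library with few low-read genes. The authors' atm-1 70 Gy means had r = 0.129 with that group gene by gene (rank 8 of 16) and an SD of differences of 3.55. With both sets of values put in rising order the SD was 0.0061, the lowest of the 16 groups (0.219 in the next), so the column holds nearly the values of this group but in another gene order. The atm-1 control means beside them fell likewise from 3.22 to 0.0416. The authors' TOP6A3-OE1_atm-2 means had r = 0.774 with that library (rank 9 of 16) and in rising order an SD of 0.742 (rank 13), so they were matched to it in neither way. In the authors' deposited table the median was -1.79 for ATM in the cold, against -1.73 here, -0.65 for atm-1 in the cold, against -0.29 here, and -0.27 for top6a3 against a control it names K3, against -0.46 here relative to the library labelled TOP6A3.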

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

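All tests in this part were chosen only after the results were seen, except that the interactions themselves and the top6a3 comparison with other wild types were planned.

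The 70 Gy response differed between atm-1 and ATM in 41 genes by an interaction test, led by OsGSTU36 (-7.50), RAD51A2 (-5.36) and ST1 (-4.95). That ATM 70 Gy replicate 3 and atm-1 control replicate 1, the libraries with few low-read genes, set the difference is argued against: without both libraries 35 of the 41 were still called in the same direction. Whether the libraries labelled atm-1 70 Gy came from unirradiated plants stays open. Of the 12 genes called in atm-1 without both libraries, 10 were also called in the same direction in ATM, where 0.319 would be shared if independent. Any other difference between 70 Gy and control libraries common to both lines would also give such sharing, so it cannot decide. Of the 106 genes that rose in ATM at 70 Gy, 48 were higher and 57 lower in atm-1 with all libraries (median -0.05). Loss of ATM remains a candidate explanation, a hypothesis: with 1 library each, the genes that rose in ATM had a median difference of -1.33 between TOP6A3-OE1_atm-2 and TOP6A3-OE1 at 40 Gy. The authors' own means for TOP6A3-OE1_atm-2 did not match that library (r = 0.774, rank 9 of 16 groups), so what the library holds is less sure. Of 100 splits of the libraries, 3 gave as many genes, the real one included (41, and 55 in the highest other), a share under 0.05. Control and 70 Gy libraries were split separately, so another split could keep the real grouping at 70 Gy. The share is therefore not a p-value.

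The splits of 3 against 3 libraries number 10, too few for a share under 0.05. ATM at 70 Gy gave 129 genes in the real split and at most 17 in another, with 1 of 10 splits as large. For atm-1 against ATM at 70 Gy these were 81 and 0, with 1 of 10 as large. For atm-1 against ATM without treatment they were 0 and 0, and for atm-1 at 70 Gy 0 and 1, each with 10 of 10 splits as large.

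The difference between top6a3 and the library labelled TOP6A3 rests on a lone library whose TOP6A3 level was 185 times that of the highest other library of its table. Of 13520 genes at 5 FPKM or more in every top6a3 library, 195 had no read in it, against 12 of 14041 the other way. With the 3 ATM controls as wild type 2149 of 3166 genes kept call and direction, but both comparisons share the top6a3 libraries. With separate libraries, of the genes called for 1 top6a3 library against the lone library, 62.5% to 63.4% were called in the same direction for the other 2 top6a3 libraries against the ATM controls. That was 4.38 to 4.70 times the number shared if independent, while opposite calls were 1.77 to 1.92 times their own number if independent. This argues against the lone library as the whole cause, though not for each gene, and ATM and top6a3 lines also differ in other ways. For the light harvesting genes called higher the lone library remains a candidate cause, as 4 of 10 were still called higher. The library may come from another line, such as an overexpressor of TOP6A3; the 185-fold level is what that would need, and a biological effect of losing TOP6A3 stays open and was not tested apart from it.

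The fall of 1633 genes in the libraries labelled ku70 at 40 Gy includes 813 with no read in either library, while 15.7% of the 654 rises had no read in either control. Missed transcripts in these libraries may account for part of the falls, the 813 being what that would give. Of the 26 photosystem genes called lower, 24 had 10 or more reads in both libraries, so these were not wholly missed. Genes with 1 to 10 reads made up only 1.81% and 1.37% of detected genes there, so that count cannot tell a partial loss from a fall. An effect of irradiation in ku70 stays open for the photosystem genes and for the rest.

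The 40 Gy response differed between ku70 and DJ in 266 genes by an interaction test, led by Os11g0645400 (9.24), RNRS2 (8.22) and OsLTP2.6 (8.09). Of the 176 with a more negative change in ku70, 155 had no read in either ku70 40 Gy library, so missed transcripts stay open for these. The count of 266 was 0 with a replicate block fitted to only the groups compared.

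The interaction of line and cold passed for 40 genes, with the largest values in Os03g0286500 (3.37), OsSCP5 (3.32) and Os03g0109350 (3.12). It has 1 cold library per line, and those genes were at or near 0 in every control, so the test holds no measure of variation between cold libraries. The count was 0 by limma-voom and 0 when only the groups compared were fitted, and a difference between the lines in the cold stays open.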

How the results depend on the processing

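The refits with limma-voom, library weights, both libraries with few low-read genes left out and a mean of 20 FPKM or more were chosen only after the results were seen. Unless stated, the cause of a change was not tested. Of 4821 alternative values of 354 named results, each a gene in a comparison (262 distinct genes), 3673 stayed on their side of the threshold, 1142 lost their call and 6 reversed, all in top6a3: with the ATM and TOP6A3 libraries, and with the ATM controls alone, as wild type, Os02g0282600 was 0.50 and 1.37 and Os12g0470000 0.98 and 2.23, and with the ATM controls alone OsLAC8 was -0.57 and OsTOP6A3 0.35. In these settings the ATM controls joined or replaced the lone library labelled TOP6A3. They also come from another line, so the reversals cannot be assigned to that lone library alone. Of 224 list tests, 98 passed with the preset correlation and 9 with an estimated one.

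Each library of the groups compared was left out in turn, unless it was the only library of its group. This gave 0 to 2 called genes for atm-1 minus ATM without treatment. At 70 Gy it gave 67 to 156 for ATM, 0 to 1 for atm-1 and 16 to 60 for their interaction. For atm-1 minus ATM at 70 Gy it gave 54 to 98. In the cold the counts were 2527 to 2683 for ATM, 3485 to 6108 for atm-1 and 30 to 46 for the interaction. For top6a3 they were 2474 to 2695 and for TOP6A3-OE1 1048 to 1080. They were 182 to 241 for ku70 minus DJ and 213 to 284 for DJ at 40 Gy. For ku70 at 40 Gy they were 443 to 2037, and for the 40 Gy interaction 249 to 420. The lone cold, TOP6A3 and TOP6A3-OE1 libraries were never left out, so these ranges do not show how far the counts rest on them.

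Replicate numbers did not pair libraries (correlations of same-numbered libraries' deviations -0.365 to 0.226). A replicate block gave 14 for ATM at 70 Gy, 0 for its interaction and 0 for atm-1 minus ATM at 70 Gy. It gave 0 for DJ at 40 Gy, 657 for ku70 at 40 Gy and 0 for the 40 Gy interaction. The block fits also held only the groups compared, so they lost the spread of the other groups. Lower counts than in the main fit are therefore not due to the block alone. Their nearer comparison is with the fits of only the groups compared, some of which are given next.

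Fits of only the groups compared, with fewer residual degrees of freedom, gave 212 for ATM at 70 Gy, 20 for the 70 Gy interaction, 0 for atm-1 in the cold, 0 for the cold interaction, 6845 for top6a3, 0 for ku70 minus DJ, 0 for DJ at 40 Gy, 3474 for ku70 at 40 Gy, 11 for the 40 Gy interaction and 151 for TOP6A3-OE1. A pseudocount of 0.1 gave 14 for the 70 Gy interaction, 17 for the cold interaction, 272 for ku70 minus DJ, 416 for DJ at 40 Gy and 741 for the 40 Gy interaction. No filter gave 514 for the cold interaction and 2457 for TOP6A3-OE1. A filter of 5 FPKM gave 3 for the cold interaction, 40 for ku70 minus DJ, 114 for DJ at 40 Gy, 118 for the 40 Gy interaction and 598 for TOP6A3-OE1. Robust moderation gave 2 for ku70 minus DJ, 1 for DJ at 40 Gy, 6 for the 40 Gy interaction and 579 for TOP6A3-OE1. For top6a3, the ATM and TOP6A3 libraries together as wild type gave 6823 (2264 of the 3166 kept) and the ATM controls 7829 (2149 kept).

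Limma-voom gave 8 for the 70 Gy interaction, 2071 and 2513 for ATM and atm-1 in the cold, 0 for the cold interaction, 1909 for top6a3, 0 for ku70 minus DJ, 77 for DJ at 40 Gy and 557 for the 40 Gy interaction. Library weights gave 4 for atm-1 minus ATM without treatment, 6033 for ATM at 70 Gy, 2649 for atm-1 at 70 Gy, 1252 for the 70 Gy interaction, 3150 for atm-1 minus ATM at 70 Gy, 11781 and 12077 for ATM and atm-1 in the cold, 1929 for the cold interaction, 11438 for top6a3, 150 for DJ at 40 Gy and 142 for the 40 Gy interaction. Without both libraries with few low-read genes the counts were 1656 for ATM at 70 Gy, 12 for atm-1 at 70 Gy, 98 for the 70 Gy interaction, 203 for atm-1 minus ATM at 70 Gy, 8736 and 8288 for ATM and atm-1 in the cold and 7965 for top6a3. A mean of 20 FPKM or more gave 27 for ATM at 70 Gy, 5 for the 70 Gy interaction, 16 for atm-1 minus ATM at 70 Gy, 1966 and 1873 for ATM and atm-1 in the cold, 0 for the cold interaction, 753 for top6a3, 5 for ku70 minus DJ, 109 for the 40 Gy interaction and 379 for TOP6A3-OE1. Depth, about 10364400 to 16477100 recovered reads per library, limits what can be said of genes with few reads, but it is not the only limit. With about 14307600 reads, ku70 40 Gy replicate 1 had 25651 genes listed at 0 and a Pearson's r of 0.7504 with replicate 2.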

Other observations

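No test in this part was planned, and each was chosen only after the results were seen. With ATM 70 Gy replicate 3 and atm-1 control replicate 1 left out, 12 genes passed in atm-1 at 70 Gy, all 12 with the sign they had in ATM. They included CAB2R (log2 4.04), the peroxidase gene prx78 (3.01, and 3.35 in ATM), OsPAL04, a phenylalanine ammonia-lyase gene (1.70), OsBBX24 (1.70) and OsG6PDH1, of the oxidative pentose phosphate pathway (1.11, and 1.15 in ATM), and Os03g0117800 among the lower ones (-0.95).

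The lines also differed in which genes had any read. Whether such genes were not transcribed, differ in sequence or are absent from a line was not tested. Of 11163 genes at 5 FPKM or more in every TOP6A3, top6a3 and atr library, 67 had no read in any ATM or atm-1 library, and of 8853 genes at 5 FPKM or more in every ATM and atm-1 library, 21 had none in any TOP6A3, top6a3 or atr library. Of 13520 genes at 5 FPKM or more in every top6a3 library, 195 had no read in the library labelled TOP6A3, and of 14041 genes at that level in the library labelled TOP6A3, 12 had none in any top6a3 library. Of 7062 genes at 5 FPKM or more in every DJ and ku70 library, 127 had no read in either TOP6A3-OE1 library, and of 11410 genes at that level in both TOP6A3-OE1 libraries, 135 had none in any DJ or ku70 library. Of 111 genes at that level in every DJ and ku70 library with no read in either TOP6A3-OE1 library and listed in both tables, 94 were under 1 FPKM in every ATM and atm-1 library, as were 141 of all 6985 such DJ and ku70 genes, and 1 was under 1 FPKM in every TOP6A3, top6a3 and atr library.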
